A study of Mus musculus with 6 samples.

How the data were processed

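Bulk RNA of whole mouse testis was measured by RNA sequencing in 6 samples, 3 labelled wild type (WT) and 3 labelled conditional knockout (cKO). The series title places the loss of SRSF2, a serine and arginine rich splicing factor, in Sertoli cells, the somatic cells of the seminiferous tubule that nurse germ cells. The age of the mice is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

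The authors deposited 1 table of FPKM values per gene, that is, reads or fragments scaled to gene length and to a total per library, with 55850 gene rows and columns for the 6 samples. Per the submitters' processing notes, the genome builds named were GRCm38 and mm10. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. The positions in the table are not those of GRCm38: of 52081 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 1499 had the same start. Positions given in the text are therefore those of GENCODE M21 on GRCm38, looked up by gene identifier, and no position of the table is printed.

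FPKM multiplied by the table's gene length was a whole multiple of 1 step per library for 100% of values within a tolerance of 0.01, so numbers of reads per gene were recovered. These came to 16070287 to 17281330 reads per library, and intervals or floors made from them cover counting error only. Genes named with their exon overlaps, near-identical globin copies and overlapping mitochondrial genes are uncertain, since how the authors' counting divided shared reads is not stated. Other named genes also share exon bases with annotated genes, among them Cdkn1a, Egfl7, Sycp3, Srpk2 and Atf5, and are uncertain in the same way.

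The main test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 1) of the 14238 genes with a mean FPKM of at least 1, cKO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Before the data were examined, the tests, groups and a rule for naming genes were fixed. The rule takes Srsf2, up to 12 genes per direction with the largest change among those past the threshold with non-overlapping groups (clone-type and pseudogene symbols left out), and up to 4 members with the lowest adjusted p of each gene list. Genes outside the rule are said to be so.

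Likewise 30 gene lists of testis cell types, splicing factors and pathways were fixed at that stage, and 28 had the minimum of 5 tested members. Each was tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry, which tests whether members move one way or, in its mixed form, either way, were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. The adjustment over a list alone does not correct for the number of lists. A list score per library is the mean over members of log2(FPKM + 1) minus the gene's mean over the 6 libraries. Lists of cytosolic ribosomal proteins and of nuclear-encoded respiratory chain subunits were added after the data were seen. Exact two-sided permutation tests of single values used every split of the 6 samples, for which the smallest p is 0.1.

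The procedure was tested on simulated data of the same 6-library comparison over 55850 genes, drawn 5 times. At the threshold, 90.5% of tested genes changed 2-fold and 99.8% of those changed 4-fold were recovered, with 12.2 false calls per draw. The simulation held independent genes and no trend shared by many genes of a library. Every gene was drawn with the same dispersion of 0.0143, and many changed genes and a shifted list were planted. The recovery rates therefore need not hold for the measured libraries.

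Other settings fixed at that stage were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, 3 other scalings, limma without trend or with robust estimation, the replicate number as a block, an added limit on fold change, and leaving out each library. Added after the data were seen were limma voom on recovered reads (at least 10 reads in at least 3 libraries), removal of each library's trend on gene length and GC content (natural splines with 5 degrees of freedom, GC from GENCODE M21 transcripts, known for 97.9% of tested genes), estimated library weights, rescaling without ribosomal, mitochondrial and haemoglobin genes, and protein-coding genes alone. Planned count-based tests were not run because the table holds FPKM. The table lists genes, not transcripts or junctions, so splicing, which the series design names, is not analysed here. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.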

Results

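The data comprised 6 whole-testis RNA libraries, 3 WT and 3 cKO, and addressed how gene expression in the testis differs when SRSF2 is lost in Sertoli cells. Depth was even, with 16070287 to 16479907 recovered reads in WT and 16185976 to 17281330 in cKO libraries. Transcripts of late germ cells were scarce. Of 28 spermatid genes in the table, 20 had a mean FPKM below 1, and the median was 0.156 FPKM. Of 28 late spermatocyte genes, 16 lay below 1 FPKM.

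Srsf2, the targeted gene, was measured first. Its FPKM was 108.5 ± 16.2 (SD, n = 3) in WT and 82.9 ± 7.70 (SD, n = 3) in cKO testis, 76.4% of the WT mean. Every cKO library (74.0, 87.3 and 87.3 FPKM) lay below every WT library (127, 96.7 and 102 FPKM). The log2 difference was -0.38 (SE 0.15, limma adjusted p = 0.384), so it did not pass over all genes, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The gene (ENSMUSG00000034120) lies on chromosome 11 at 116849901 to 116853094 of GRCm38, minus strand, and shares exon bases with Mettl23 and Mfsd11 on the opposite strand. Cells other than Sertoli cells also express Srsf2, and the deleted part is not given in the labels, so a remaining level in whole testis does not measure the deletion itself.

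Across all genes, 1 gene fell and 1 rose in cKO testis. Tmem114, which encodes a transmembrane protein, fell from 8.75 ± 1.27 to 2.07 ± 0.274 FPKM (SD, n = 3), a log2 difference of -1.66 (SE 0.14, 95% interval -1.99 to -1.34, limma adjusted p = 0.0355). It lies on chromosome 16 at 8409275 to 8425136 of GRCm38, minus strand, and its exons overlap no other annotated gene. The rise was in Gm35082, a long non-coding RNA gene outside the naming rule and chosen after its values were seen, on chromosome 7 at 100675088 to 100677760, plus strand. It had 0 recovered reads in each WT library and 41, 32 and 26 in the cKO libraries, at least 32.2-fold higher against a floor of 3 reads over the WT group (limma adjusted p = 0.0486). It was the 1 gene of the table with no WT read and at least 10 reads in each cKO library, and 0 genes showed the opposite pattern.

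At an unadjusted p under 0.05, 662 genes were higher and 1094 lower, a balance that turned with scaling, to 900 and 741 on the TPM scale and 1122 and 640 when rescaled without rRNA, mitochondrial and haemoglobin genes. It was 467 and 628 without WT replicate 3, 1057 and 1341 without cKO replicate 1, 237 and 529 without cKO replicate 2, and 269 and 480 without cKO replicate 3. The groups did not overlap for 2650 of 14238 tested genes, 18.6%. The average over all splits of the samples is 10%. Shares of the other splits were not counted and genes vary together, so the excess does not measure an effect of genotype. Leaving out any 1 of the 6 libraries gave 0 genes, with adjusted p of Tmem114 between 0.0679 and 0.266 and its log2 difference between -1.77 and -1.59. Gm35082 passed in 6 of the 19 other settings that tested it, so that median-of-ratios scaling and the TPM scale gave 0 higher and 1 lower gene, and limma voom on recovered reads, added after the data were seen, gave 1 gene, Gm35082, at an adjusted p of 0.00600.

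Sertoli cell markers were lower in cKO testis. Amh, the anti-Müllerian hormone of immature Sertoli cells, was at 768 ± 144 FPKM in WT and 383 ± 64.1 in cKO (SD, n = 3), 49.9% of the WT mean. Cst9, a cystatin gene, was at 166 ± 32.3 and 81.2 ± 7.42 FPKM, a log2 difference of -1.01. Aard was at 166 ± 33.6 and 97.4 ± 10.2 FPKM, and Shbg, the sex hormone binding globulin gene, had a log2 difference of -0.66 and a cKO mean of 5.93 ± 0.307 FPKM.

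Of 33 tested Sertoli markers, 29 had a negative log2 difference, the median was -0.33, and the list fell as a set (camera adjusted p = 6.06e-09). The call was lost, at an adjusted p = 0.594 with an estimated correlation. That was the lowest adjusted p of all fixed lists tested, so no list passed in that form. By fry the adjusted p was 0.0512 for one direction and 0.0239 for change in either direction. Adjusted over the list alone 9 members fell and 0 rose (Cst9 and Shbg 0.0111, Amh 0.0130, Aard 0.0268), while over all genes 0 passed, the lowest adjusted p being 0.306 for Cst9. That tally of 9 was 2 without WT replicate 3, 1 without cKO replicate 2, 0 without cKO replicate 3 and 10 to 13 without 1 of the other libraries. The share of reads from 18S ribosomal RNA also differed, at 1.58 to 2.09% in the WT libraries and 0.727 to 0.835% in the cKO libraries. The list score was 0.17 ± 0.11 in WT and -0.17 ± 0.01 in cKO (SD, n = 3), with no overlap (exact permutation p = 0.1). Of the 33 members, 9 also stand in another fixed list. The related lists of junctions and signals did not pass. Among 21 blood-testis barrier genes (camera adjusted p = 0.527), Cldn11, a tight junction claudin, had a log2 difference of -0.42 and Marveld2, a tricellular junction gene, 0.45. Among 18 Sertoli-to-germ-cell signals (camera adjusted p = 0.253), Inhbb stood at -0.41, Wnt6 at -0.47 and Gdnf, the stem cell growth factor, at -0.44. Over the other settings Inhbb ranged from -0.52 to -0.17, Wnt6 from -0.58 to -0.17 and Gdnf from -0.56 to -0.32. In both lists 0 members passed adjusted over the list alone and 0 over all genes, but without WT replicate 1, 2 barrier genes passed over the list alone.

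**Figure D1:**
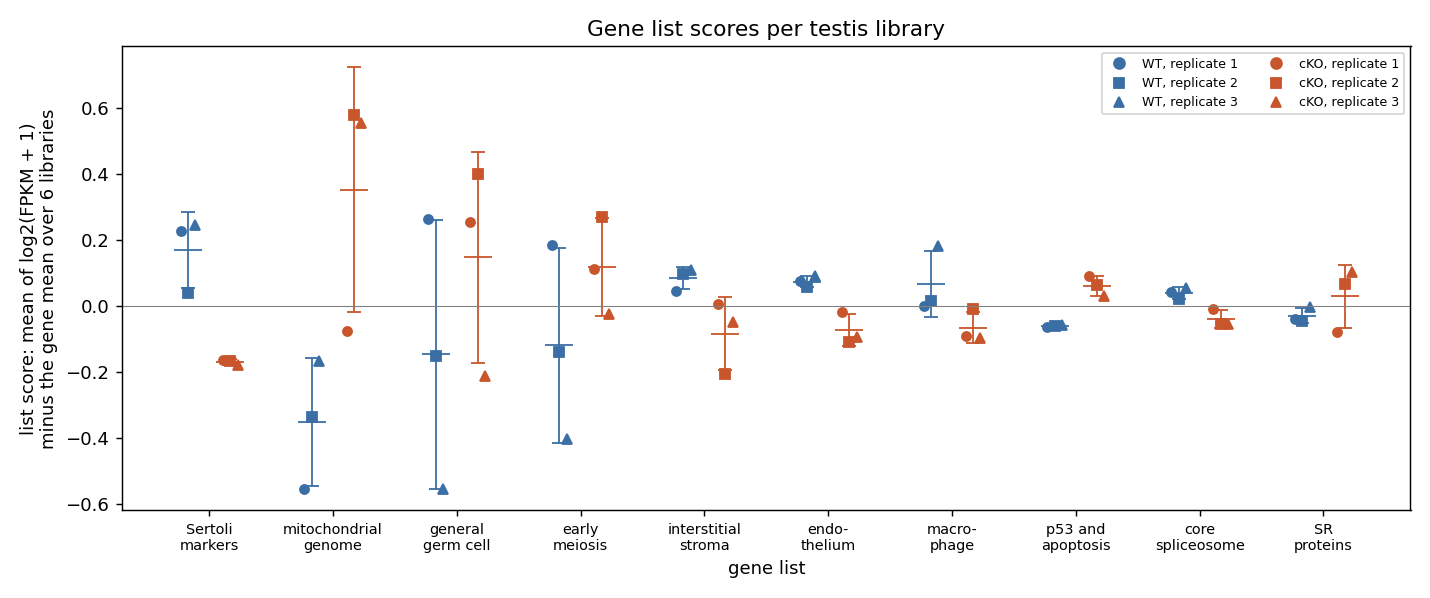
List scores (vertical axis, mean of log2(FPKM + 1) over list members minus each gene's mean over 6 libraries) for 10 gene lists (horizontal axis). Points are single libraries, blue for WT and orange for cKO, and bars are the mean ± SD of 3 libraries. Sertoli marker scores were 0.17 ± 0.11 in WT and -0.17 ± 0.01 in cKO with no overlap, whereas general germ cell scores overlapped.

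Among p53 targets and apoptosis genes, 4 of 22 rose when adjusted over the list alone, which does not correct for the choice among 28 lists. Ccng1, a cyclin gene induced by p53, rose from 16.8 ± 1.77 to 28.6 ± 1.08 FPKM and Trp53inp1 from 4.97 ± 0.605 to 8.65 ± 0.690 FPKM (SD, n = 3), adjusted over the list alone (limma adjusted p = 0.00492 and 0.00531). Eda2r, an ectodysplasin receptor gene, and Cdkn1a, the p21 cell cycle inhibitor, also rose by that adjustment (0.0422 and 0.0468), from 1.02 ± 0.421 to 2.46 ± 0.594 and from 1.31 ± 0.0854 to 2.23 ± 0.224 FPKM. The other 18 of 22 members did not pass, and over all genes 0 passed, with an adjusted p of 0.306 for Ccng1. The tally of 4 was 3 without WT replicate 2 and 2 without each of the other 5 libraries, on the TPM scale, without a filter or with a mean FPKM of at least 5. The list did not pass against other genes (camera adjusted p = 0.198, median log2 difference 0.08), while fry gave an adjusted p of 0.0512 for one direction and 0.000166 for change in either direction. For one direction no list passed by fry. For either direction the Sertoli and ovarian lists (both 0.0239), the mitochondrial and macrophage lists (both 0.0427) and core spliceosome (0.0480) passed too. List scores did not overlap, at -0.06 in each WT library and 0.03 to 0.09 in cKO. Scores of 7 of the 30 lists did not overlap, where any split averages 10%. These included macrophage, endothelium and core spliceosome, which camera did not call. With length and GC trends removed, Trp53inp1 went from 0.69 to 0.42, while the p53 list had a camera adjusted p of 0.0302. The 18S share and GC trends also differed between the groups and were not told apart from genotype.

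Transcripts of the mitochondrial genome were higher in cKO testis. All 12 tested genes had a positive log2 difference, with a median of 0.68, and the list rose as a set (camera adjusted p = 5.51e-08). The call was lost with an estimated correlation (adjusted p = 0.690). By fry the adjusted p was 0.0843 for one direction and 0.0427 for either direction. Adjusted over the list alone 8 members rose and 0 fell, and over all genes 0 passed. That tally of 8 was 0 without WT replicate 3, cKO replicate 2 or cKO replicate 3, and 0 without a filter or with length and GC trends removed. mt-Nd2 was at 1050 ± 64.1 FPKM in WT and 1678 ± 259 in cKO (SD, n = 3), mt-Nd6 at 879 ± 119 and 1412 ± 172, mt-Atp6 at 59.6 ± 9.75 and 104 ± 22.8, and mt-Co3 at 88.0 ± 7.09 and 127 ± 20.5. mt-Nd6 overlaps mt-Nd5 on the opposite strand, and mt-Atp6 overlaps mt-Atp8 and mt-Co3. Mitochondrial genes took 1.83 ± 0.163% of recovered reads in WT and 2.76 ± 0.319% in cKO (SD, n = 3). The 18S ribosomal RNA gene Rn18s-rs5, chosen after its values were seen, took 1.77 ± 0.276% and 0.791 ± 0.0566% (limma adjusted p = 0.360 for its FPKM). With length and GC trends removed, a correction chosen after the data were seen, the median of the list fell to 0.38.

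Germ cell and meiotic genes were higher as sets by camera at the preset correlation, with wide spread between libraries. Of the 10 splits of the samples, counting the real one, 5 gave a camera p as small for germ cell genes and 6 for early meiosis genes. Of 20 tested general germ cell genes 17 had a positive difference (median log2 0.35, camera adjusted p = 0.00408), and of 26 early meiosis genes 21 did (median 0.21, camera adjusted p = 0.00439). Both calls were lost, at an adjusted p = 0.728 with an estimated correlation, and 0 members of either passed over all genes or adjusted over the list alone. By fry for one direction the adjusted p was 0.656 for germ cell and 0.616 for early meiosis genes. Without WT replicate 1, 8 germ cell and 2 early meiosis members passed over the list alone, and without WT replicate 2, 1 early meiosis member. Tex14, needed for the bridges between germ cells, was at 12.6 ± 1.06 FPKM in WT and 18.2 ± 2.84 in cKO (SD, n = 3), and Dazl, a germ cell RNA-binding protein gene, at 24.8 ± 5.62 and 35.7 ± 7.01. Tex15 stood at 8.54 ± 2.76 and 14.0 ± 1.22 FPKM and Sycp3, of the synaptonemal complex, at 4.34 ± 1.55 and 6.78 ± 1.89. Germ cell scores of the libraries overlapped between groups, from -0.55 to 0.26 in WT and -0.21 to 0.40 in cKO. Early meiosis scores overlapped too, from -0.40 to 0.19 in WT and -0.03 to 0.27 in cKO. The germ cell call ended without WT replicate 3 (adjusted p = 0.319), cKO replicate 1 (0.107) or cKO replicate 2 (0.0716), and the meiosis call without WT replicate 3 (0.319), cKO replicate 2 (0.0716) or with length and GC trends removed (0.0768). The germ cell median was 0.14 without WT replicate 3, 0.18 without cKO replicate 2 and 0.53 without cKO replicate 3. The meiosis median was 0.10 without WT replicate 3, 0.39 without WT replicate 1 and 0.34 without cKO replicate 3.

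Among spermatogonial and later germ cell lists, none passed. Undifferentiated spermatogonia (17 genes, camera adjusted p = 0.247) included Foxo1 at a log2 difference of 0.25, and differentiating spermatogonia (13 genes, 0.588) included Scml2 at 0.50. Late spermatocytes (12 genes, 0.568) included Tdrd5 at 0.38, and their median of -0.02 differed in sign from their mean of 0.05 and from the test. Without WT replicate 1 that median was 0.25, with 9 of 12 genes positive, and without WT replicate 3 the test direction turned. Spermatids (8 genes, 0.943) included Crem at 0.24, with a median of -0.04 and a mean of -0.01 against a test direction of up. With 16 of 28 late spermatocyte and 20 of 28 spermatid genes below a mean FPKM of 1, few members were tested. The tests of these stages therefore cannot decide whether they differ. In each of these 4 lists 0 members passed over all genes or adjusted over the list alone.

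Interstitial stroma genes fell as a set and red blood cell genes rose as a set. Of 18 stroma genes 13 had a negative difference (median log2 -0.15, camera adjusted p = 0.0358), at an adjusted p = 0.728 with an estimated correlation. Gsn was at 48.3 ± 2.79 FPKM in WT and 35.5 ± 5.01 in cKO (SD, n = 3), Fbln1 at 57.2 ± 3.07 and 45.7 ± 3.40, and Tcf21 at 129 ± 28.2 and 92.1 ± 10.9. All 7 blood genes had a positive difference (median log2 0.69, camera adjusted p = 0.0102), likewise at an adjusted p = 0.728 with an estimated correlation. By fry for one direction the adjusted p was 0.264 for stroma and 0.612 for blood genes. Hbb-bs, an adult beta globin gene with near-identical copies, was at 1807 ± 464 FPKM in WT and 2872 ± 431 in cKO (SD, n = 3). Haemoglobin genes took 0.310 ± 0.110% of recovered reads in WT and 0.461 ± 0.0694% in cKO (SD, n = 3). In both lists 0 members passed over all genes or adjusted over the list alone. The stroma call ended without WT replicate 2 (0.193), WT replicate 3 (0.0940) or cKO replicate 2 (0.254) and under 5 other settings given with the alternatives, and the blood call without WT replicate 1 (0.0755) or WT replicate 2 (0.145) and with library weights (0.438). The stroma median was -0.07 without cKO replicate 2 and -0.03 with quantile normalization, and the blood median 0.23 with library weights. Without WT replicate 3, 6 blood genes passed over the list alone.

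Other cell types of the testis showed no list past the threshold by camera. By fry for either direction the macrophage and ovarian lists passed (adjusted p = 0.0427 and 0.0239). Of 12 macrophage genes (camera adjusted p = 0.226), C1qa and C1qb, which encode complement components, fell adjusted over the list alone (0.0199 and 0.0263), from 7.53 ± 0.734 to 4.52 ± 0.767 and from 7.35 ± 0.652 to 5.13 ± 0.315 FPKM (SD, n = 3), and 0 members passed over all genes. That tally of 2 was 1 without WT replicate 1, 0 without WT replicate 3 or cKO replicate 3, and 0 on the TPM scale, with voom, with rescaling or with length and GC trends removed. Endothelial genes (13 genes, 0.166) had a median log2 difference of -0.15, with Egfl7 at -0.61 and Tie1 at -0.28. Leydig and steroid synthesis genes (23 genes, 0.437) went both ways, with Lhcgr, the luteinising hormone receptor gene, at 0.51 and Tspo at -0.50. Cholesterol synthesis genes (23 genes, 0.527) also went both ways, with Pmvk at -0.68 and Idi1 at 0.53. Peritubular myoid genes (12 genes, 0.226) included Tpm2 at -0.50, and basement membrane genes (17 genes, 0.238) included Lamb2 at -0.39. Antigen presentation (8 genes, 0.286) included H2-Ab1 at -0.43, interferon response (8 genes, 0.828) included Ddx58 at 0.29, and ovarian somatic genes (7 genes, 0.828) included Rspo1 at -0.39. In the lists of this paragraph other than macrophages 0 members passed over all genes or adjusted over the list alone. Without WT replicate 2, 1 cholesterol and 1 myoid gene were past the list threshold on the lower side, and without cKO replicate 1, 1 cholesterol gene on the higher side.

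Among core splicing factors 1 gene rose and 1 fell. Ptbp2, a splicing repressor, rose from 6.26 ± 0.309 to 10.7 ± 1.34 FPKM and Snrnp70, of the U1 particle, fell from 25.7 ± 3.04 to 16.9 ± 1.73 FPKM (SD, n = 3), adjusted over the list alone (limma adjusted p = 0.0119 and 0.0271). Neither passed that way without WT replicate 3, cKO replicate 2 or cKO replicate 3. On the TPM scale and with rescaling 1 member rose and 0 fell. The remaining 22 of 24 core spliceosome genes did not pass that way, 0 of 24 passed over all genes, and the list did not pass (camera adjusted p = 0.238, median log2 -0.09). By fry its adjusted p was 0.0843 for one direction and 0.0480 for either direction. Of 21 SR proteins and relatives 15 had a positive difference (median log2 0.06, camera adjusted p = 0.247), with Srpk2, an SR protein kinase gene, at 0.32, and 0 passed over all genes or adjusted over the list alone.

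**Figure D2:**
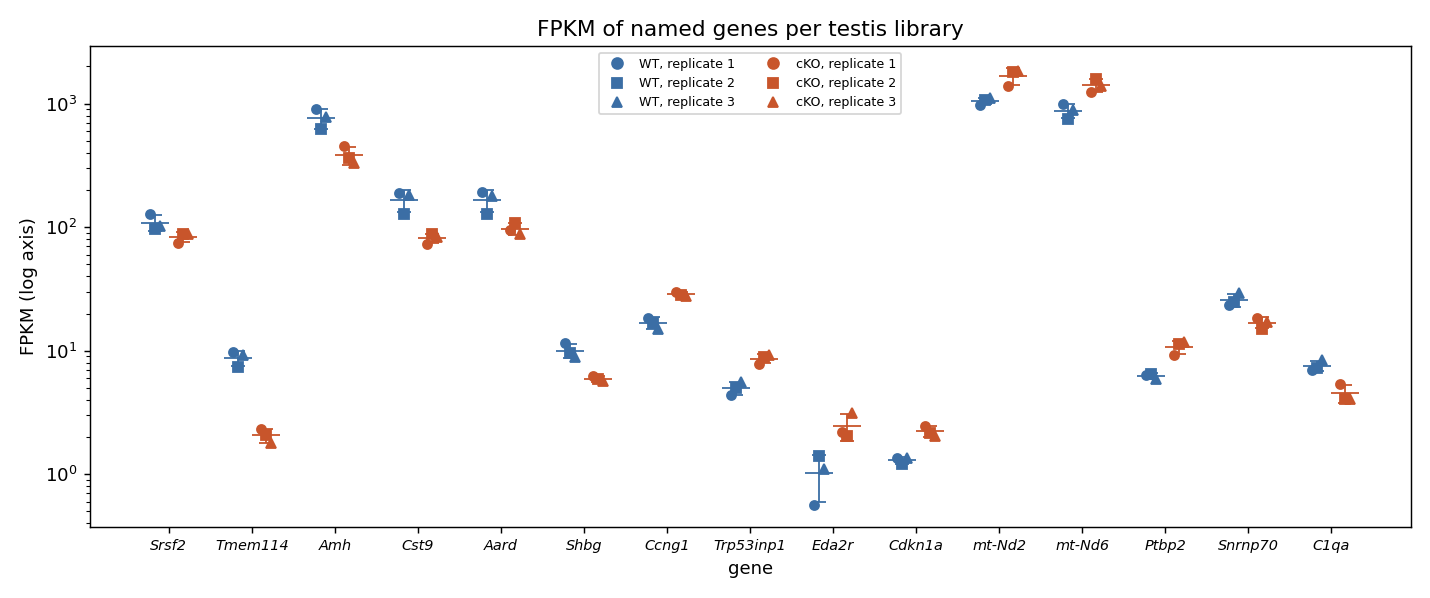
FPKM on a log axis (vertical) of 15 named genes (horizontal), with single libraries as points, blue for WT and orange for cKO, and bars for the mean ± SD of 3 libraries. Amh stood at 768 ± 144 FPKM in WT and 383 ± 64.1 in cKO, Ccng1 at 16.8 ± 1.77 and 28.6 ± 1.08.

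Of the remaining lists, proliferation (27 genes, camera adjusted p = 0.329) included Bub1 at a log2 difference of 0.33 and Plk1 at -0.31, and the stress response (16 genes, 0.828) included Atf5 at -0.33. Immediate early genes, which rise with tissue handling (11 genes, 0.668), included Btg2 at 0.36, and retinoic acid genes (17 genes, 0.226) included Rarg at -0.34. In these 4 lists 0 members passed over all genes or adjusted over the list alone. Epididymis and rete testis genes (4 tested) and replication histones (3 tested) were too few for a test, and of the 15 epididymis and rete genes 11 had a mean FPKM below 1.

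Libraries also differed in GC and length trends. Across genes, the deviation of a library from the mean of all 6 correlated with GC content at a Spearman rho of 0.26, 0.34 and 0.43 in the WT libraries and 0.16, -0.59 and -0.56 in the cKO libraries, so the groups did not overlap and cKO replicates 2 and 3 stood apart. With log gene length, rho was -0.48 in WT replicate 1 and between -0.12 and 0.34 in the other 5. Genes are not independent replicates, and no p is given for these correlations. Correlations of log2 values between libraries were 0.960 to 0.974 within WT, 0.972 to 0.977 within cKO and 0.944 to 0.982 between groups.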

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

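The 5 settings chosen after the data were seen are voom, the length and GC correction, library weights, rescaling and the protein-coding set. The main result was 2 genes, 1 higher and 1 lower. It was 1 (0 higher, 1 lower) with pseudocounts of 0.1 or 0.5, a mean FPKM of at least 5, median-of-ratios scaling, the TPM scale or protein-coding genes, 0 without a filter, and 0 in each fit without 1 library. Quantile normalization gave 2 (1 higher, 1 lower), of which 1 was shared with the main result. Voom gave 1 (1 higher, 0 lower), the length and GC correction 3 (2 higher, 1 lower), and library weights 680 (189 higher, 491 lower), with WT replicate 3 weighted 3.87 and WT replicate 1 0.315. Genes higher and lower at an unadjusted p under 0.05 numbered 662 and 1094 at first, 1058 and 999 of 17780 tested genes with voom, 1005 and 1411 without a filter, 417 and 878 at FPKM 5, 392 and 704 with the length and GC correction and 1941 and 2488 with weights. The 2 genes also passed an absolute log2 difference of at least 1. Fewer samples remain when a library is left out. The other causes were not tested. With the replicate number as a block the count was 0, the stroma list had an adjusted p of 0.0639, and the tallies over the list alone went from 9 to 3 for Sertoli, 4 to 2 for p53, 8 to 2 for mitochondrial, 2 to 0 for macrophage, 2 to 0 for core spliceosome, 0 to 2 for blood, 0 to 1 for differentiating spermatogonia and retinoic acid and 0 to 3 for respiratory chain genes. Other tallies over the list alone that left 0 were, without WT replicate 2, 24 respiratory chain and 27 ribosomal protein genes (all lower), 1 blood gene on the TPM scale, with voom, the length and GC correction or rescaling, 2 cholesterol genes with voom, and 1 respiratory chain gene with quantile normalization, voom, rescaling or protein-coding genes. With library weights, members on the higher and lower side went from 0 and 0 to 10 and 0 for germ cell, 11 and 0 for early meiosis, 1 and 0 for differentiating spermatogonia, late spermatocytes and proliferation, 2 and 5 for barrier, 1 and 5 for Sertoli signals, 1 and 4 for cholesterol, 2 and 2 for stress, 0 and 4 for stroma and myoid, 0 and 2 for basement membrane, endothelium and ovarian, 0 and 9 for respiratory chain and 2 and 15 for ribosomal protein genes. Same-numbered libraries correlated at 0.09, -0.33 and 0.39 in their deviations, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Of the lists, 3 (without cKO replicate 2) to 7 passed without 1 library and 5 to 8 in the other settings. Sertoli and mitochondrial lists passed in all 21 settings (highest adjusted p 8.09e-07 and 0.000413). Lost calls were early meiosis at 0.0768 with the length and GC correction, blood at 0.438 with library weights, and stroma at 0.142 with a mean FPKM of at least 5, 0.0719 on the TPM scale, 0.344 with quantile normalization and 0.0874 with rescaling. Without 1 library the adjusted p ranged from 1.57e-08 to 0.319 for general germ cell, 3.15e-07 to 0.319 for early meiosis, 1.01e-07 to 0.145 for blood and 0.0132 to 0.254 for stroma. Directions of lists that had not passed turned as follows, by adjusted p, where a range covers all 6 fits without 1 library, turned or not: spermatids (0.801 without a filter, 0.899 quantile, turned at 0.982, 0.831 and 0.915 without WT replicates 2 and 3 and cKO replicate 2, range 0.766 to 0.987), stress response (0.946 TPM, 0.890 quantile, 0.960 voom, 0.221 length and GC, 0.590 weights, 0.853 rescaled, turned at 0.242 and 0.972 without WT replicate 1 and cKO replicate 3, the ends of the range), ovarian genes (0.989 at FPKM 5, 0.685 length and GC, turned at 0.901 without WT replicate 3, range 0.612 to 0.982), immediate early (0.0768 length and GC, turned at 0.989 without WT replicate 1, range 0.517 to 0.989), SR proteins (0.355 length and GC), Leydig (0.590) and cholesterol synthesis (0.739) with weights, and, in 1 fit each, cholesterol synthesis at 0.964 without WT replicate 1 (range 0.235 to 0.964), without WT replicate 2 barrier at 0.982 (0.184 to 0.982) and basement membrane at 0.982 (5.98e-06 to 0.982), and without WT replicate 3 differentiating spermatogonia at 0.489 (0.0924 to 0.990), late spermatocytes at 0.724 (0.0755 to 0.894) and interferon at 0.901 (0.517 to 0.972). Lists that gained a call were p53 (0.0302), core spliceosome (0.00663) and undifferentiated spermatogonia (0.00663) with the length and GC correction, basement membrane with weights (0.00644) and without WT replicate 1 (5.98e-06), undifferentiated spermatogonia without cKO replicate 3 (0.0277), Leydig without WT replicate 3 (0.0299) and macrophage at FPKM 5 (0.0349). Srsf2 kept its direction and stayed above the threshold in all 21 settings, from -0.46 to -0.26, and named genes kept their direction in every setting that tested them. Their size moved. Without 1 library, Scml2 went to 0.32 and Sycp3 to 0.33 (WT replicate 3), Crem to 0.13 (WT replicate 2), Tcf21 to -0.30, H2-Ab1 to -0.27 and Btg2 to 0.24 (WT replicate 1), Lamb2 to -0.25 (cKO replicate 2) and Atf5 to -0.20 (cKO replicate 3). The length and GC correction moved many named genes by over 1.5 times, among them Amh to -0.65, Wnt6 to -0.17, Dazl to 0.21, C1qa to -0.34, Ptbp2 to 0.43, Trp53inp1 to 0.42, mt-Nd6 to 0.36 and Atf5 to -0.04. Isoform and count-based alternatives were not run. Depth of 41 to 218 reads per library limits Tmem114.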

Other observations

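Tests of length and GC bias and all counts over splits of the samples were chosen after the results were seen, while the tests of single libraries and of the spread of Sertoli markers were written before their results were seen, although the number of lists passing without each library was known. Lists of cytosolic ribosomal proteins (83 genes, median log2 -0.22, camera adjusted p = 2.15e-05) and of nuclear-encoded respiratory chain subunits (76 genes, median -0.18, 3.37e-06), added after the data were seen, were lower in cKO testis. Both calls were lost with an estimated correlation (adjusted p = 0.776 and 0.738) and without WT replicate 1 (0.823 and 0.198), where both medians were -0.04. The medians were -0.40 and -0.37 without WT replicate 2, and library scores of both lists overlapped between groups. The mitochondrially encoded transcripts, by contrast, had a median of 0.68.

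By camera at the preset correlation, the lower Sertoli marker levels were not removed by either technical test. With length and GC trends removed, all 33 members having a value, the median went from -0.33 to -0.23 and the camera adjusted p was 1.79e-10. Length and GC bias could thus account for part of the fall. The camera adjusted p went from 6.06e-09 to 1.79e-10 while the median shrank, so it does not show how large that part is. With an estimated correlation the list passed neither before (adjusted p = 0.594) nor after (0.124), so this test cannot exclude such bias for the rest. The highest adjusted p with 1 library left out was 8.09e-07. Other splits of the samples also gave small camera p for this list, down to 0.000133, so that p alone does not decide. The median stayed between -0.41 and -0.28 with 1 library left out, so the lower median did not rest on a single library. Adjusted over the list alone, however, fewer members passed without WT replicate 3, cKO replicate 2 or cKO replicate 3. A lower share of Sertoli cells may lower all markers alike. The SD of member log2 differences was 0.32, at the 63.6th percentile of 10000 lists of like expression (median SD 0.30), so fewer Sertoli cells and lower transcript levels per cell cannot be told apart here, and with an 18S share of 0.727 to 0.835% in cKO against 1.58 to 2.09% in WT libraries, RNA handling or library preparation stays open and untested beside genotype.

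By camera at the preset correlation, the higher mitochondrial transcripts were likewise not removed by either test. Adjusted over the list alone, however, no member passed with the trends removed or without WT replicate 3, cKO replicate 2 or cKO replicate 3. With the trends removed, all 12 members having a value, the median went from 0.68 to 0.38 and the camera adjusted p was 2.15e-06. Length and GC bias could thus account for part of the rise. With an estimated correlation the list passed neither before (adjusted p = 0.690) nor after (0.371), so this test cannot exclude such bias for the rest. List scores were 0.58 and 0.55 in cKO replicates 2 and 3, whose GC rho was -0.59 and -0.56. They were -0.08 in cKO replicate 1 and -0.17 in WT replicate 3. The highest adjusted p with 1 library left out was 1.09e-06. The lower 18S share in the same cKO libraries leaves a difference in RNA handling or library preparation open beside genotype, and neither was tested.

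The higher germ cell and meiotic sets rest on few libraries. The highest adjusted p with 1 library left out was 0.319 for both lists, without WT replicate 3, so variation between single libraries may account for both calls. With length and GC trends removed, the general germ cell list had an adjusted p of 0.00183 (0.719 with an estimated correlation, median 0.35 before and 0.23 after), while the early meiosis list moved to 0.0768 (median 0.21 with an SD over members of 0.26 before, 0.11 with 0.16 after). Why the meiosis call ended was not tested. A biological difference in germ cell content stays open and untested.

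With 3 samples against 3, the 10 splits of the 6 samples are too few for a share under 0.05. The real split gave 2 genes, and the highest of the other splits gave 18 (WT replicates 1 and 2 with cKO replicate 1), with 3 of 10 splits giving at least 2. For lists, the real split gave 6 and the highest other 8, with 5 of 10 splits giving at least 6. In the split with 18, the red blood cell list had a camera p of 7.09e-11. Its scores divided the same way, from -1.01 to -0.26 in those libraries and from 0.65 to 0.84 in the others. The split may thus point to a structure among the samples, whose cause was not tested. Of the 9 other splits, 6 gave 0 genes. The real split had the smallest camera p of the 10 for Sertoli markers (2.16e-10 against 0.000133 for the next), mitochondrial transcripts (3.94e-09 against 3.95e-06) and stroma (0.00768 against 0.0139), that is, 1 of 10 splits as small for each. For general germ cell genes 5 of 10 splits gave a p as small as the real 0.000437, the smallest other being 2.53e-18. For early meiosis 6 of 10 were as small as 0.000627 (smallest other 1.15e-10), and for red blood cell genes 4 of 10 as small as 0.00181 (smallest other 7.09e-11).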
